A study of Caenorhabditis elegans with 2 samples.

How the data were processed

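NFYA-1-GFP chromatin immunoprecipitation followed by sequencing was measured in whole late embryos of 1 transgenic strain, with 2 biological replicates per the labels. Chromatin was sheared by sonication, per the labels. Per the labels' descriptions the antibody was against GFP, while the antibody field names the factor itself. The labels give separate biological samples for the replicates and no batch.

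The authors deposited peak lists in narrowPeak format, in builds ce11 and ce10, per the listings deposited with them. Per the same listings, the lists per replicate and the pooled list hold peaks and background regions meant as input to a reproducibility analysis (IDR). They were derived from the alignments of each replicate, or of both, and from 1 further file that the listings also give as a source of control-normalized signal. The peak list holds the regions that passed that analysis. Regions were thus called per replicate and on pooled replicates. Each region's signal value, as the authors deposited it, is a positive enrichment signal of the caller, whose scale is not given in the sources used here; it was used to rank, describe and filter regions within 1 list. The deposited q-value is given per region as −log10 and was not used for any test; the field for a p-value is filled with -1 throughout. The aligner, the peak caller, its thresholds and the value of the reproducibility threshold are not given in the sources used here. Control data, read alignments and signal tracks were not used here, so the depth per sample is unknown, the number of reads behind a peak cannot be given, and differences in depth between replicates could change the lengths of their lists.

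The choices of tests, promoter window, gene lists, alternatives and the rule for named genes were made before the data were examined, except where the text says otherwise. Coordinates are 1-based and in ce11, whose chromosomes match WBcel235; all 4098 peaks ended within its chromosome lengths. Genes came from Ensembl release 115 and sequence from the RefSeq copy of WBcel235. The 14 mitochondrial peaks were left out of tests against genes and sequence. A promoter was 500 bp upstream to 100 bp downstream of any of 29314 starts of protein-coding transcripts of 19973 genes, and a gene with a summit there was called bound; a peak could be given to more than 1 gene, which happened for 465 of the 1812 peaks at promoters. Summits were sorted into promoter, 5' UTR, coding exon, 3' UTR, intron (any other part of a coding gene, exons of its non-coding transcripts included) and intergenic, in that order. Replicates were compared by the summits of their 4098 strongest regions within 100 bp of each other, and by whether the summit of a peak lay within a region of the replicate's list, with no minimum overlap of regions. Shuffles moved each summit to a random position of its chromosome 1000 times with a fixed seed, without regard to mappability.

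CCAAT was searched on both strands within 50 bp of the summit and within the same width 500 bp to one side, chosen at random, of the same summit. Ratios for all strand-merged 5-mers used flanks on both sides. Gene lists (29, of which 416 of 419 individually listed names matched the annotation, the others being gene families taken by name pattern) were tested with Fisher's exact test against all other coding genes, with Benjamini-Hochberg adjustment over the lists; odds ratios have Woolf intervals, and 7 genes stood in more than 1 list. Each test treats genes as independent, although neighbouring genes can share a peak. The named genes were those at the 20 strongest peaks, all NF-Y subunit and Hox genes, for each other list past the threshold the 4 bound members with the highest signal (all if 5 or fewer), and for other lists at most 2. Genes near other strong peaks and ced-7 were named after their values were seen. Since any transcript start counted, a promoter can lie within a gene. This held for the peaks of lin-39, drap-1, hsp-90, atg-9 and ajm-1, among others.

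Added after the data were seen were the splits of peaks by promoter and by family, the test between peaks at and away from coding promoters, and the search for families. Windows of 178 bp to each side of the summits were aligned to each other with blastn 2.17.0 (E-value at most 1e-08, at least 50 bp), and peaks linked by any alignment formed a family. A majority sequence was taken over peaks with same-strand CCAAT boxes whose starts are 32 bp apart, and ungapped copies with at most 8 mismatches over its 33 positions outside the boxes were searched in the nuclear genome. The majority sequence itself comes from bound copies with both boxes. A copy was bound when a summit lay within 100 bp of its middle.

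The functions were tested on simulated data. With boxes put into random windows of the 4084 simulated peaks, 36.2% of peaks were expected to hold CCAAT and 36.2% were found to, and 5.50% of 200 sets without an effect gave p under 0.05. The simulated summits lay at random positions, without the GC difference between summits and flanks of the real peaks. That rate may therefore not hold for the real peaks. For promoter position, 39.2% was expected and 39.3% recovered, with 3.50% of 200 sets without an effect under 0.05. Those sets were made by the same shuffling as the null, so a rate near 5% was set in advance. It does not speak for real peaks. With 5 lists bound 4 times as often as the other genes, 95.3% of raised lists of 20 or more genes were found among 19973 genes, and 0.396% of the other lists were called. Each gene was drawn independently there, while real peaks can be shared by several genes, so these rates may not hold for the real lists. For summits shared between replicates, 60.5% was put in and 60.9% recovered. All of 400 simulated copies of a repeated sequence were found, and none elsewhere, in 5000000 bases. A difference of 20 percentage points between copies was recovered as 20.2. Binding was simulated there without regard to how the sequence was found. The real sequence was derived from bound copies, so this recovery may not hold for the real difference. Alternatives covered the upper 50% of peaks by signal, the list of either replicate alone, the ce10 lists, overlap rules, promoter windows, nearest starts, motif windows, control windows and distances. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, networkx 3.6.1 and matplotlib 3.10.9.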

Results

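The data describe where NFYA-1, a subunit of the NF-Y complex that binds CCAAT boxes, was found on the Caenorhabditis elegans genome in late embryos. Chromatin was taken from whole hermaphrodite embryos of strain OP404, which carries a transgene for NFYA-1 fused at its C terminus to a GFP-FLAG tag, and was precipitated, per the labels' descriptions, with an antibody against GFP. There was 1 group with 2 biological replicates, so no comparison between conditions was possible, and the measurements were peak lists rather than read counts. The list of peaks that passed the authors' reproducibility threshold, called here the peak list, held 4098 regions in genome build ce11 (WBcel235), with a median width of 356 bp and signal values from 58.2 to 9543. Of these, 4084 lay on the 6 nuclear chromosomes and entered every comparison with genes and sequence. The longer list made from both replicates pooled held 15515 regions, and the lists of replicate 1 and replicate 2 held 21476 and 28596 regions. The 4098 peaks were the 4098 regions with the highest signal in the pooled list. Read depth is unknown, since the lists carry no read counts, and intervals given below cover counting error over peaks or genes.

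The same promoters headed both replicates' lists, with Y22D7AL.10 ranked 1, the bidirectional mdt-26 and ift-43 promoter ranked 2 and the BiP gene hsp-3 ranked 3 in each. The 20 strongest peaks of the peak list ranked no lower than 20 in replicate 1 and 27 in replicate 2. Of the 4098 peaks, 4067 (99.2%) had their summit inside a region of replicate 1 and 4056 (98.98%) inside a region of replicate 2. Those lists also hold background regions. Counting only the 4098 strongest regions of each replicate, the shares were 89.2% and 88.6%. Among the 4098 strongest regions of each replicate, 76.5% of the summits of replicate 1 lay within 100 bp of one of replicate 2, against a mean of 0.875% for shuffled summits (two-sided permutation p = 0.002, the smallest that 1000 shuffles can give). Across the 4027 peaks found in both lists, signal values had a Spearman rho of 0.774, a value across peaks, which are not independent replicates. The peak list is the top of the list made from both replicates pooled, so its shares within their lists and this rho are not independent of how it was made.

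The peak with the highest signal (9543, summit at III:1619136) was 207 bp upstream of the start of Y22D7AL.10 (WBGene00021248, III:1617151 to 1618929), which encodes a homologue of the mitochondrial co-chaperonin HSP10. Promoters of 5 genes in the list of endoplasmic reticulum chaperones, drawn up before the data were seen, were among the 20 strongest peaks: hsp-3 (WBGene00002007, signal 5097, summit at X:6092180), the calreticulin gene crt-1 (WBGene00000802, signal 3414, summit at V:6100812), the protein disulfide isomerase genes pdi-2 (WBGene00003963, signal 2478, summit at X:4524126) and pdi-6 (WBGene00015168, signal 1287, summit at X:7068579), and the GRP94 homologue enpl-1 (WBGene00011480, signal 2381, summit at IV:11119233). The cytosolic chaperone gene hsp-90 shared the peak ranked 5 (signal 3579, summit at V:14685795) with C47E8.4. The others at promoters were mdt-26 and ift-43 (signal 5564), sor-1 (3580), imp-2, which shared the peak of enpl-1, the cytochrome oxidase subunit gene cox-5B (1501), the actin gene act-4 (1494), the ribosomal protein gene rpl-3 (1347), drap-1 (1200) and wwp-1 (1117).

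CCAAT stood within 50 bp of the summit in each of the 9 strongest peaks, those of hsp-3, crt-1, pdi-2, enpl-1 and hsp-90 included, and in 14 of the 20 strongest (70.0%, 95% Wilson interval 48.1 to 85.5). The peaks of cox-5B, rpl-3 and drap-1 held none. Of the 20, 14 lay at promoters of protein-coding genes and the other 6 did not. Those 6 lay upstream of ubql-1 (summit at I:7021452, 520 bp from the start, signal 3361), sop-2 (II:12339327, 617 bp), spo-11 (IV:11125400, 538 bp) and ain-1 (X:16612439, 1012 bp), in the 5' UTR of egl-30 (I:1837052) and between genes on chromosome IV (IV:15571064), with Y105C5A.1 as the nearest coding gene.

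Genes of protein synthesis, respiration and protein breakdown were bound more often than other genes. A summit lay from 500 bp upstream to 100 bp downstream of a transcript start of 2233 of the 19973 protein-coding genes (11.2%), which are called bound. Of the 80 cytosolic ribosomal protein genes, 69 (86.3%) were bound, against 10.9% of all other genes (odds ratio 51.4, 95% interval 27.2 to 97.3; Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 3.74e-53 over 29 lists). This share depended on how peaks were given to genes: with the promoter of 250 bp upstream to 50 bp downstream 19 of 80 were bound (23.75%, odds ratio 4.003), and with each peak given to its nearest start alone 43 of 80 (53.75%, odds ratio 12.2). Their strongest members were rpl-3, rpl-15 (signal 990), rpl-20 (984) and rpl-35 (707). Of the respiratory chain and ATP synthase genes, 24 of 38 were bound (63.2%, adjusted exact p = 2.53e-13), led by cox-5B, cox-5A (694), atp-1 (505) and cox-6B (374). Of the proteasome genes, 21 of 33 were bound (63.6%, adjusted exact p = 6.44e-12), led by pas-4 (775), rpn-3 (349), rpn-5 (228) and rpn-9 (163). Of the translation factors and tRNA synthetases, 31 of 71 were bound (43.7%, adjusted exact p = 2.12e-11), led by eef-1A.1 (455), iff-2 (431), ife-2 (374) and eef-1A.2 (339). Of the mitochondrial ribosomal protein genes, 19 of 66 were bound (28.8%, adjusted exact p = 0.000216), led by mrps-7 (198), mrpl-49 (176), mrpl-17 (172) and mrpl-45 (166). The peaks of rpl-15, rpl-20, atp-1, cox-6B, eef-1A.1 and all 4 named genes of the proteasome and of the mitochondrial ribosome also lay at the promoter of another coding gene, in the case of mrpl-49 the cytosolic ribosomal protein gene rpl-28. A gene was called bound with or without CCAAT. In the order given, 13 of 69, 3 of 24, 3 of 21, 4 of 31 and 0 of 19 bound genes held it near the summit. Other bound genes held it in 19.5% to 19.7% of cases. Promoter signal that does not depend on the factor cannot be told apart here, as described below.

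**Figure D1:**
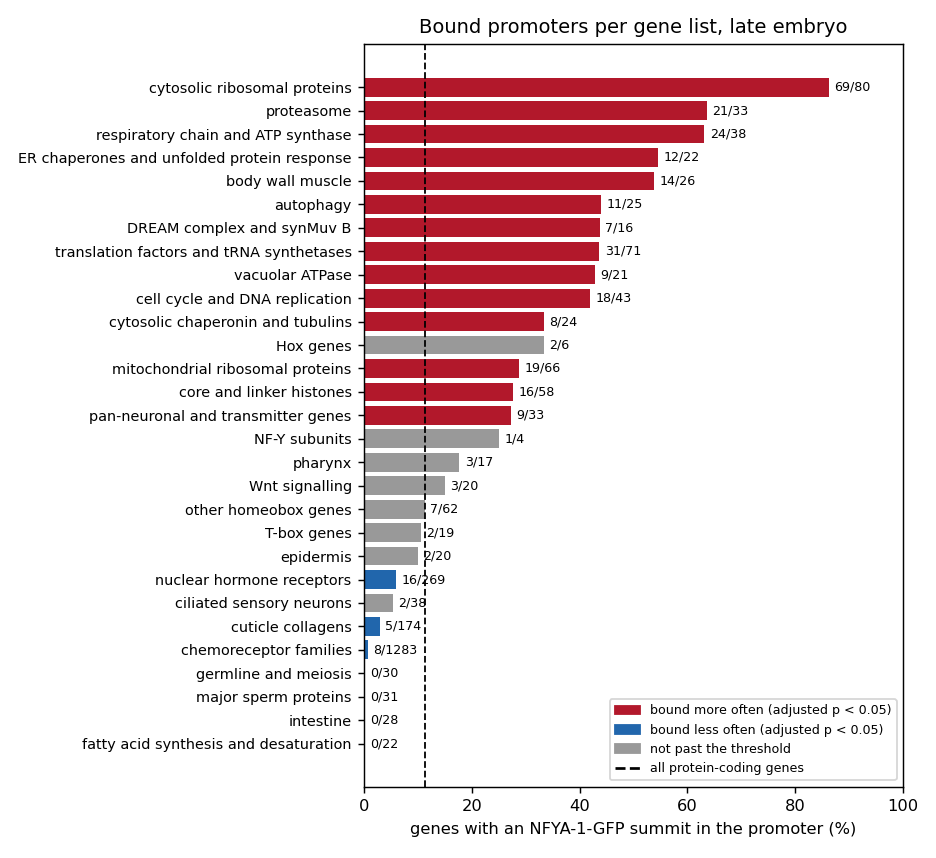
Share of genes in each list with an NFYA-1-GFP summit in the promoter window (horizontal axis, percent), with the number bound of the number in the list beside each bar and the share over all protein-coding genes (11.2%) as a dashed line. With this window cytosolic ribosomal protein genes were at 86.3%, against 23.75% with the narrower one and 53.75% with nearest starts, and chemoreceptor families were at 0.624%.

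Other lists bound more often than the rest of the genes covered folding, the cell cycle, chromatin and muscle. Of the endoplasmic reticulum chaperone and unfolded protein response genes, 12 of 22 were bound (54.5%, adjusted exact p = 2.96e-06), with hsp-3, crt-1, pdi-2 and enpl-1 in the lead. The chaperonin and tubulin list had 8 of 24 bound (33.3%, adjusted exact p = 0.00659), led by tba-2 (485), cct-8 (466), cct-1 (337) and cct-7 (308). The cell cycle and DNA replication list had 18 of 43 bound (41.9%, adjusted exact p = 1.11e-06), led by the topoisomerase gene top-2 (423), cdc-6 (144), pcn-1 (133) and wee-1.3 (127). The list of the DREAM complex and synMuv B genes, which repress germline and cell cycle genes, had 7 of 16 bound (43.8%, adjusted exact p = 0.00205), led by lin-9 (573), lin-53 (447), lin-54 (316) and efl-1 (242). Of the core and linker histone genes, 16 of 58 were bound (27.6%, adjusted exact p = 0.00102), led by his-67 and his-68, which share a peak (394), hil-7 (349) and his-37 (332). Body wall muscle genes had 14 of 26 bound (53.8%, adjusted exact p = 5.78e-07), led by act-4, unc-112 (323), unc-60 (232) and the MyoD homologue hlh-1 (163). Autophagy genes had 11 of 25 bound (44.0%, adjusted exact p = 0.000107), led by lgg-2 (253), atg-18 (148), atg-9 (139) and epg-2 (135). Vacuolar ATPase genes had 9 of 21 bound (42.9%, adjusted exact p = 0.000542), led by vha-8 (404), vha-12 (240), vha-15 (230) and vha-1 (212). Pan-neuronal and transmitter genes had 9 of 33 bound (27.3%, adjusted exact p = 0.0146), led by unc-86 (138), rgef-1 (103), ric-19 (91.2) and ida-1 (88.5). The peaks of enpl-1, cct-8, cct-1, cct-7, top-2, cdc-6, lin-53, unc-60, vha-8, vha-1 and ric-19 were shared with another coding gene, and that of lin-54 with the ribosomal protein gene rpl-12.

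Chemoreceptor genes were bound less often than other genes, at 8 of 1283 (0.624% against 11.9% of other genes, adjusted exact p = 3.37e-54), with sri-5, srh-2, srh-16 and srh-269 the strongest at signals from 132 to 244. The peak of sri-5 was shared with rsr-1. Cuticle collagen genes were also bound less often, at 5 of 174 (2.87%, adjusted exact p = 0.000238), namely col-38, col-2, col-71, col-107 and dpy-17; col-38 shared its peak with rpl-5 and col-2 with the kinetochore gene ndc-80, and col-71 also shared its peak. Nuclear hormone receptor genes were bound in 16 of 269 cases (5.95%, adjusted exact p = 0.00820), nhr-49 (482), nhr-1 (374), nhr-47 (177) and nhr-32 (155) being the strongest, with the peak of nhr-47 shared. In all, 14 lists were bound more often, 3 less often and 12 did not pass the threshold. No gene was bound in the lists of germline and meiosis genes (0 of 30, which allows a share of up to 10%; adjusted exact p = 0.0661), major sperm proteins (0 of 31, up to 9.68%; adjusted exact p = 0.0661), intestine (0 of 28, up to 10.7%; adjusted exact p = 0.0973) and fatty acid synthesis and desaturation (0 of 22, up to 13.6%; adjusted exact p = 0.217), but none of these differences passed the threshold. These upper limits are 3 divided by the number of genes, a one-sided approximation unlike the two-sided intervals given elsewhere. They do not by themselves place these lists below other genes.

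Among the remaining lists, the counts were 3 of 17 for pharynx genes (adjusted exact p = 0.503), with tbx-2 (signal 241) and eya-1 (161), and 2 of 19 for T-box genes (adjusted exact p = 1), with tbx-2 and mab-9 (181). Ciliated sensory neuron genes had 2 of 38 bound (adjusted exact p = 0.503), the RFX gene daf-19 (194) and dyf-3 (102), whose peak was shared. Wnt signalling genes had 3 of 20 (adjusted exact p = 0.540), with mig-14 (615) and sys-1 (172), other homeobox genes 7 of 62 (adjusted exact p = 1), with ceh-38 (334, a shared peak) and ceh-93 (284), and epidermis genes 2 of 20 (adjusted exact p = 1), with ajm-1 (73.7) and mup-4 (70.7). The call for the pan-neuronal list was lost without replicate 1 (adjusted exact p = 0.133) and with either other promoter window (adjusted exact p = 0.0579 and 0.0596); in the upper 50% of peaks by signal its odds ratio was 0.519. With that shorter list the cell cycle and autophagy calls were lost (adjusted exact p = 0.0646 and 0.0915), with the promoter of 250 bp upstream to 50 bp downstream the chaperonin and vacuolar ATPase calls (0.744 and 0.111), and with each peak given to its nearest start alone the chaperonin, histone and nuclear hormone receptor calls (1, 0.0680 and 0.0948). Some calls were kept while the odds ratio moved by more than 1.5 times. With the promoter of 250 bp upstream to 50 bp downstream, 14 of 38 respiratory genes were bound (odds ratio 7.49 in place of 13.8) and 7 of 26 body wall muscle genes (4.71 in place of 9.32), while the histone list rose from 3.04 to 4.89. With each peak given to its nearest start alone, the respiratory list had an odds ratio of 8.36. In the upper 50% of peaks by signal, 5 of 26 body wall muscle genes were bound (3.97), while the odds ratios rose to 16.8 for endoplasmic reticulum chaperones (from 9.58), 6.88 for chaperonin and tubulin genes (from 3.98) and 10.02 for DREAM genes (from 6.20). The autophagy list fell from 6.27 to 3.68 without replicate 1. For lists bound less often, the odds ratio of nuclear hormone receptors was 0.312 in the upper 50% by signal in place of 0.499, that of collagens 0.118 with nearest starts in place of 0.233, and that of chemoreceptors ranged from 0.0278 to 0.0719 over the promoter windows.

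Of the 4 NF-Y subunit genes, nfyc-1 (WBGene00017742, II:43907 to 44917) was bound, with a summit 12 bp upstream of its start (signal 79.9, ranked 2921) and without CCAAT, in a peak shared with the proteasome gene rpt-4. The genes nfya-1, nfya-2 and nfyb-1 were not bound, their nearest summits lying 12.9, 21.4 and 8.85 kb from a transcript start. Of the 6 Hox genes, which pattern the body axis, lin-39 and egl-5 were bound, both with CCAAT. The peak of lin-39 (WBGene00003024, III:7528641 to 7536632, signal 390, ranked 189) had its summit at III:7534923, within the gene. That summit lay 118 bp upstream of an internal transcript start. For egl-5 (WBGene00001174, III:7814374 to 7817141) the signal was 103.6, ranked 2158. The nearest summits to nob-1 (790 bp), ceh-13 (863 bp) and mab-5 (1057 bp) lay upstream beyond the promoter window, and the nearest to php-3 was the one of nob-1, 7.55 kb upstream. Neither list passed the threshold (1 of 4, adjusted exact p = 0.476; 2 of 6, adjusted exact p = 0.191; Fisher's exact test, two-sided). With the promoter window widened to 1000 bp upstream and 200 bp downstream, 4 of the 6 Hox genes were bound, and this list passed it (adjusted exact p = 0.00837).

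Peaks away from the promoters of protein-coding genes held the CCAAT box more often than their surroundings. No such difference was found for peaks at those promoters, without regard to GC content. Over all 4084 peaks, 1342 had CCAAT within 50 bp of the summit (32.9%, 95% Wilson interval 31.4 to 34.3), against 19.9% of windows 500 bp away from the same summits (exact McNemar test, two-sided, p = 1.90e-41). Away from coding promoters it was 973 of 2272 peaks (42.8%, flanks 19.5%, exact p = 1.22e-67), and at coding promoters 369 of 1812 (20.4%, flanks 20.9%, p = 0.744). Promoters of genes that were not bound held CCAAT in 17.4% of windows around a point 100 bp upstream of the start, against 20.4% of the peaks at promoters (Fisher's exact test, two-sided, p = 0.00214). Peaks at coding promoters held CCAAT less often than the other peaks (odds ratio 0.341, 95% interval 0.296 to 0.393; Fisher's exact test, two-sided, p = 2.42e-53), and without the largest family of similar peaks, described below, the odds ratio was 0.574 (0.489 to 0.673; p = 7.38e-12). The split by promoter was chosen after the data were seen. Without that family, 18.2% of peaks at coding promoters held CCAAT, and no difference from the promoters of genes that were not bound was found (Fisher's exact test, two-sided, p = 0.429). Summit windows at coding promoters, family included, had a GC content of 47.8%, against 33.9% at the promoters that were not bound. Neither comparison with those promoters took this into account.

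By ratio of shares in summit windows to flanks, CCAAT ranked 131 among all strand-merged 5-mers (ratio 1.66). CGCGC (24.6% against 4.36%), CGCCC (26.6% against 5.31%) and CGCAG (30.3% against 6.81%) led the ranking, and CTCTC was at 44.7% against 12.7%. Summit windows had a GC content of 48.2% and flanks of 35.8%. Among the 30 strand-merged 5-mers with the base composition of CCAAT, a comparison added after the data were seen, CCAAT ranked 4, with a median ratio of 0.821 over the 30. At coding promoters it ranked 7 of those 30, with a ratio of 1.02 to the flanks on both sides and a median of 0.697 over the 30. Without the largest family of similar peaks, described below, it ranked 8 there, with a ratio of 0.901 and a median of 0.691.

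The largest family of similar peak sequences held 39.3% of all peaks with CCAAT, and 291 of its peaks had a pair of boxes at a fixed spacing. When the sequences around the summits were aligned to each other, this family held 555 peaks (13.6%), of which 527 (95%) had CCAAT; 331 lay in introns, 137 between genes and 63 at coding promoters. Without this family, CCAAT was found in 23.1% of peaks against 19.2% of flanks (exact McNemar test, p = 5.25e-05), and away from coding promoters in 27.9% against 18% (p = 2.88e-12). Same-strand boxes whose starts lay 32 bp apart were counted 360 times within 150 bp of all summits, against 24 times around points 1000 bp away, and 349 of the 360 were in the family. The majority sequence over the peaks with such a pair was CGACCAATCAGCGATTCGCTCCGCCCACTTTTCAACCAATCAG, 43 bp long. The copy with both boxes under the strongest peak lay in an intron of ced-7 (III:9571028 to 9571070, plus strand, signal 988) and read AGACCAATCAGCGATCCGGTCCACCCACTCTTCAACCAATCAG.

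**Figure D2:**
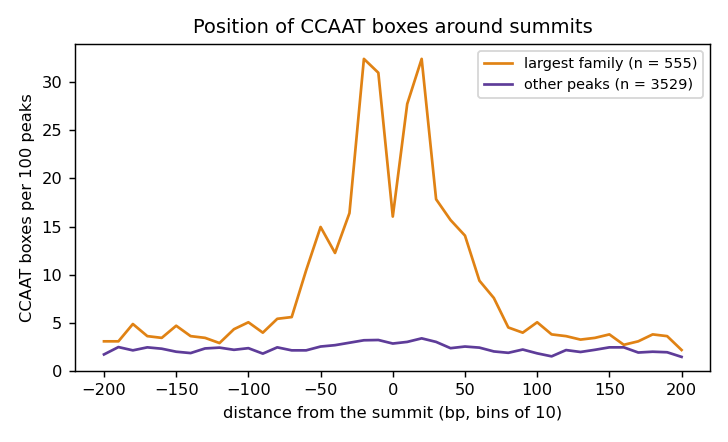
CCAAT boxes per 100 peaks on either strand (vertical axis) by distance from the summit in bins of 10 bp (horizontal axis), for the 555 peaks of the largest family of similar sequences and for all other peaks. In the family, boxes are densest to either side of the summit, and in the other 3529 peaks their density is higher near the summit by a smaller amount.

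Stronger peaks held CCAAT more often. The share fell from 46.4% (95% Wilson interval 43 to 49.8) among the 817 peaks with the highest signal to 25.25% (22.4 to 28.3) among the 816 with the lowest, with 35.7%, 30.5% and 26.4% in the groups between (Fisher's exact test of highest against lowest, two-sided, p = 4.48e-19). At coding promoters the shares were 25.9% in the strongest group and 15.5% in the weakest (exact p = 0.000663), and away from them 61.8% and 32.8% (exact p = 1.94e-18). Without the largest family the difference over all peaks was 6.77 percentage points in place of 21.1 (27.8% against 21%, exact p = 0.00354). Away from coding promoters it was then 9.55 points in place of 28.9 (35.1% against 25.6%, exact p = 0.00707). At coding promoters it was 7.10 points in place of 10.4 (22.0% against 14.9%, exact p = 0.0191). With the family kept and CCAAT counted within 100 bp of the summit, the difference over all peaks was 11.45 points (54.2% against 42.8%, exact p = 4.06e-06).

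**Figure D3:**
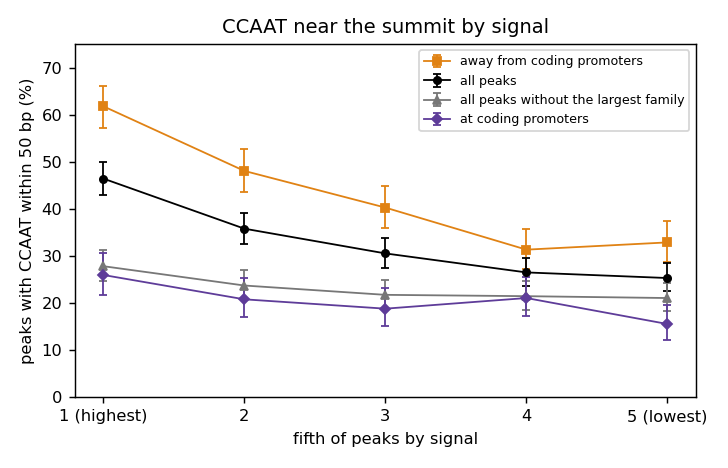
Share of peaks with CCAAT within 50 bp of the summit (vertical axis, percent) in 5 equal groups of peaks ordered by signal (horizontal axis); bars are 95% Wilson intervals. The share is 61.8% in the strongest group away from coding promoters (35.1% without the largest family, not drawn) and 25.9% in the strongest group at coding promoters.

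Promoters were the annotation most enriched for summits. Of the 4084 summits, 1812 (44.4%, 95% Wilson interval 42.9 to 45.9) lay in a promoter window, against a mean of 13.97% over shuffles within chromosomes (two-sided permutation p = 0.002, the smallest that 1000 shuffles can give). Coding exons held 15 summits (0.367%, shuffles 22.0%), introns 924 (22.6%, shuffles 31.6%) and 3' UTRs 37 (0.906%, shuffles 2.80%), each with the same p. Intergenic sequence outside the promoter windows held 1271 (31.1%, shuffles 28.9%, permutation p = 0.00799), and 5' UTRs 25 (0.612%, shuffles 0.685%, permutation p = 0.673).

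Genes on the X chromosome were bound slightly less often than autosomal genes, at 269 of 2731 (9.85%) against 1964 of 17242 (11.4%; odds ratio 0.850, 95% interval 0.743 to 0.972; Fisher's exact test, two-sided, p = 0.0170). By chromosome, 16.7% of genes were bound on I, 9.83% on II, 17.1% on III, 10.6% on IV and 6.93% on V. The share on X was thus close to that on II and above that on V, so a low share was not particular to X. The strongest X-linked promoters were those of hsp-3, pdi-2, act-4 and pdi-6. The difference between X and autosomes was not found in replicate 1 alone: without replicate 1 the odds ratio was 0.818 (exact p = 0.00313), and without replicate 2 it was 1.03 (exact p = 0.687). It was also lost in the upper 50% of peaks by signal (odds ratio 0.937, exact p = 0.504) and without the largest family of similar peaks (0.879, exact p = 0.0641).

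Genes for tRNAs had peaks more often than shuffled positions would give, in a test planned as a check on specificity. Whether the signal there depends on the factor was not tested. A summit lay within 200 bp of 170 of the 612 nuclear tRNA genes (27.8%, shuffles 1.83%; two-sided permutation p = 0.002, the smallest that 1000 shuffles can give). The share was 14.5% for summits within the genes themselves and 13.2% for the upper 50% of peaks by signal. The 159 peaks at tRNA genes held CCAAT in 29 cases (18.2%), against 33.5% of the other 3925 peaks (Fisher's exact test, two-sided, p = 3.23e-05). The largest family of similar peaks, of which 95% had CCAAT, was not left out here. Over all peaks without that family the share was 23.1%. Whether the difference at tRNA genes holds without the family was not tested.

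The counts of peaks around the genes tied to the transgene did not pass the threshold. The strain carries a tagged copy of nfya-1 and a mutation in unc-119, a common rescue marker for such transgenes. Within 20 kb of nfya-1 (X:11944285 to 11946838) lay 4 peaks and 7 regions of the pooled list, and within 20 kb of unc-119 (III:10902641 to 10908935) 2 peaks and 11 regions. Around 1000 random genes the medians were 1 peak and 6 regions and the 95th percentiles 5 and 14 (one-sided permutation p = 0.149 and 0.448 for nfya-1, 0.466 and 0.182 for unc-119). Within 10 kb of nfya-1 both counts were 0, while 8 regions of the pooled list lay within 10 kb of unc-119, against a median of 3 (one-sided permutation p = 0.0849).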

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

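Peaks on the mitochondrial genome were left out of the comparisons with genes and sequence. The peak list held 14 of them, which covered 33.0% of its 13794 bp with signals from 71.9 to 563. The pooled list held 16 mitochondrial regions, the list of replicate 2 held 23, and the list of replicate 1 held 0. What drew attention was a signal outside the nuclear comparisons, in the list of 1 replicate and not of the other. No explanation for it was tested.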

How the results depend on the processing

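Of the alternatives for counts, shares and tests that answer a comparison, 70 kept their result. That is the same direction and side of the threshold, or a count within 1.5 times. These 70 include all those for replicate overlap, promoter position, CCAAT by signal and tRNA genes. For tRNA genes no alternative left out the largest family. Within 10 kb of nfya-1 the counts were 0 in the peak list and 0 in the pooled list, below the medians of random genes, and for unc-119 the count was 0 in the upper 50% of peaks by signal; the cause was not tested. The splits by promoter and without the largest family were chosen after the data were seen. At coding promoters the CCAAT share was 20.4%, and 18.2% without the largest family, both below their flanks (20.9% and 20.2%). The higher GC content of summit windows was not taken into account there. Against flanks on both sides the ratio of CCAAT was 1.02, and 0.901 without the family. The medians over 5-mers of its base composition were 0.697 and 0.691. The odds ratio for X against autosomes was 0.937 in the upper 50% of peaks by signal, 0.879 without the largest family, and ranged from 0.818 to 1.03 with a replicate left out; the cause was not tested. With the promoter of 1000 bp upstream to 200 bp downstream, 5 lists were bound less often in place of 3, major sperm proteins (Fisher's exact test, adjusted p = 0.0273) and intestine (0.0398) being added. For single lists, with or without a call, 181 alternatives kept the direction and the side of the threshold, 9 lost a call in the same direction, 3 gained it and 10 changed direction. In the upper 50% by signal the odds ratios were 0 for NF-Y subunits (0 of 4 bound), 1.96 for T-box genes and 0.519 for pan-neuronal genes. They were 1.5 for T-box genes with the promoter of 250 bp upstream to 50 bp downstream, 2.04 for epidermis genes with the wider one, and 0.909 for Wnt genes without the largest family. With each peak given to its nearest start they were 1.20 for T-box, 1.14 for epidermis and 0.931 for chaperonin and tubulin genes. Epidermis genes ranged from 0.868 to 2.12 with a replicate left out; the cause was not tested. Of the lists that changed direction, the pan-neuronal and chaperonin lists had passed the threshold and lost their calls there. Depth is unknown and may limit the list of either replicate; in ce10 the peak list held 4107 regions and 76.8% of summits were shared, so these results differed little between builds.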

Other observations

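The tests in this part were chosen after the results were seen, those on copies of a sequence found in the data included, except the tests of low signal by the difference between groups of peaks, of tRNA genes and of the transgene. The 5 distinct peaks nearest to the 6 Hox genes all held CCAAT within 50 bp of the summit, against 32.8% of the other 4079 peaks, and 0 of the 5 belonged to the largest family of similar sequences. They were the peaks of lin-39 and egl-5 and those upstream of nob-1, ceh-13 and mab-5. Among the bound genes of 18 lists with at least 4 bound members, those of the cytosolic ribosomal protein and endoplasmic reticulum chaperone lists were ranked higher than bound genes at large past the adjusted threshold. Their median ranks were 685 and 541 (540.5) against 2018 over all bound genes (permutation test, two-sided, p = 2e-05, the smallest that 100000 permutations can give, and p = 0.001; adjusted p = 0.00036 and 0.009). The DREAM list and the chaperonin and tubulin list had median ranks of 557 and 649.5 and did not pass it (permutation test, adjusted p = 0.0636 for each). CCAAT was present at 13 of 69 bound ribosomal protein genes (18.8%) and 5 of 12 chaperone genes (41.7%), against 19.5% and 19.4% of other bound genes, and neither list passed the adjusted threshold (Fisher's exact test, two-sided, adjusted p = 1 and 0.395). None of the 19 bound mitochondrial ribosomal protein genes held it (Fisher's exact test, p = 0.0356, adjusted p = 0.395).

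Peaks were densest on chromosomes III and I, at 60.1 and 54.9 per Mb, and sparsest on V, at 27.1 per Mb. A second family of similar sequences held 2.74% of the peaks, of which 18 (16.07%) had CCAAT, 54 lay between genes and 34 in introns.

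Most peaks, 2742 of 4084, had no CCAAT within 50 bp of the summit. Regions of low signal near the threshold may account for part of this: the share with CCAAT was 21.1 percentage points higher in the strongest than in the weakest of 5 groups, though by 6.77 points without the largest family and 11.45 with CCAAT counted within 100 bp. They cannot be the whole of it, since 53.6% of the strongest group also lacked CCAAT. Signal at tRNA genes covers little of it, as 4.74% (95% Wilson interval 4.01 to 5.6) of the peaks without CCAAT lay there. Peaks without CCAAT lay at coding promoters 25.13 percentage points more often than peaks with it (52.6% against 27.5%), and 13.7 points without the largest family, which may reflect promoter signal that does not depend on the factor, or recruitment of NFYA-1 to promoters without the box; these cannot be told apart without other factors measured in the same way, which are not analysed here.

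Copies of the paired-box sequence were found at 523 places in the nuclear genome, 342 of them in introns, and 373 (71.3%) held a summit within 100 bp, against 0.819% of all nuclear positions. With both boxes intact, 295 of 379 copies were bound (77.8%), with 1 box 75 of 136 (55.1%) and with neither 3 of 8 (37.5%). Between both boxes and 1 box, at equal numbers of mismatches outside the boxes, the difference was 18.5 percentage points (bootstrap 95% interval 8.02 to 28.3; permutation test, two-sided, p = 0.00026). Against neither box it was 32.7 points (-6.07 to 68.7; permutation p = 0.137), where 8 copies are too few to decide. The sequence was itself derived from bound peaks with both boxes, under which 314 of the 523 copies lay. The share of 71.3% was thus set in large part by that choice. For the same reason, mapping and binding that depends on the boxes cannot be told apart by either difference.

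Added transgene copies could raise the number of regions near nfya-1 or unc-119. The lowest of the 4 one-sided permutation p-values within 20 kb was 0.149, and within 10 kb it was 0.0849, for unc-119, while the counts at nfya-1 were 0 there. With counts above the medians of random genes within 20 kb of both loci an effect of added copies is neither shown nor excluded.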
